A study of Mus musculus with 6 samples.

How the data were processed

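Chromatin accessibility was measured by ATAC-seq in 6 libraries of mouse colon cancer organoids of the AKP genotype. ATAC-seq uses the Tn5 transposase to cut and tag open chromatin, so the number of reads over a region rises with its accessibility. Per the labels' protocols, organoids were dissociated, 50000 cells per library were incubated with the transposase at 37 °C for 30 min, and the purified DNA was amplified by PCR. Sequencing was paired-end, with 2 reads of 75 bases per fragment. Replicates 1 to 3 of the naive group and replicates 1 to 3 of the primary tumour group were assigned from the sample titles.

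The authors deposited 1 table of read counts per peak for all 6 libraries, with no normalization of the counts. The submitters' processing notes list Bowtie, Picard, SAMtools, MACS2 and bedtools, with neither versions nor roles, and the genome build mm9. Chromosome 1 coordinates in the table reached 196957877. Peak names in the table, per the file itself, describe peaks over all samples, so 1 shared peak set was counted in every library. The table held 43020 peaks on 21 chromosomes, with peak numbers up to 108089, so that many numbers had no peak in the table. The rule that chose the peaks, any shift of read ends for the transposase offset, and the treatment of PCR duplicates are not given in the sources used here. Each of these can change counts. The peaks were wide (median 746 bp, range 200 to 6777 bp), and a shift of a few bases moves few reads across the edge of such a peak. Duplicates left in would inflate counts most in libraries with little starting material. Each peak also carried the authors' score, which ran from 5.00 to 5096.93 with a median of 21.8 and was used here only to describe peaks. Start and end are printed as the table gives them, and whether the start counts from 0 or from 1 is not given in the sources used here.

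No peaks touched or overlapped, and the smallest gap between neighbours was 801 bp. Joining touching peaks into regions, and joining peaks up to 500 bp apart, therefore both left 43020 regions, and peak and region mean the same below. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Peaks were kept by filterByExpr at its default settings, which left 36179 peaks tested and 6841 not tested. Libraries were scaled by TMM, with factors between 0.922 and 1.05. Primary tumour libraries were tested against naive libraries with edgeR's robust quasi-likelihood F test, 2-sided, with group as the sole term. P-values were adjusted by the Benjamini-Hochberg method over all tested peaks, and a peak was called at an adjusted p under 0.05. Log2 fold changes are primary tumour minus naive. Their standard errors (SE) were computed from the fold change and the F statistic. Normalized counts are CPM, each count taken relative to its library total after TMM scaling. The fitted fold change of a peak with counts near 0 in 1 group depends on the prior count that edgeR adds.

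The peaks named in the text were chosen by a rule. They had an adjusted p under 0.05, an absolute log2 fold change of at least 1, all 3 libraries of 1 group above all 3 of the other, and a mean count of at least 20 per library. The 12 highest and the 12 lowest log2 fold changes among them were named, together with the chromosomes with the highest and the lowest share of called peaks. For each chromosome and each window of 10 Mb, the median over tested peaks of log2(CPM + 1) minus the naive mean was taken in each library. They were planned as a description without a test. A test was added after the data were seen, with limma on the medians of peak values taken relative to their mean over the libraries used, with group as the sole term and Benjamini-Hochberg adjustment over 263 windows of at least 20 peaks or over 20 chromosomes. Each naive library is part of the naive mean, so the naive spread around it is understated.

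The groups, the tests, the rule for named peaks and most alternatives were fixed before the data were examined. The alternatives were total-count scaling, DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a filter of at least 20 counts in at least 3 libraries, the replicate number as a block, each library left out in turn, abundance-trended (loess, span 0.3) offsets, an offset per library and 10 Mb window, a test against a fold change of 2 (glmTreat), and autosomes alone. The fit without chromosomes 4, 5, 13, 18 and 19, the trended offsets for the chromosome medians and their pseudocount of 5 CPM were added after the data were seen. The grouping of called peaks into runs was also chosen after the calls were seen. A run was a series of at least 4 consecutive tested peaks called in the same direction, each within 50 kb of the next.

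The test was checked on simulated counts for this comparison, drawn for the 36179 tested peaks. The filter, applied again, left 34343 of them, and the shares below leave out changed peaks that it removed. Of peaks changed by a log2 fold of 0.5, 1, 2 and 3, it called 2% of 50, 19.1% of 47, 70.8% of 48 and 89.8% of 49, in no case in the wrong direction. Of 34149 unchanged peaks it called 4. Far fewer peaks were changed there than were called in the data, so the adjusted threshold was stricter and these shares do not carry over to the data.

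No genome or annotation of mm9 was used here. The gene table at hand follows GRCm38, so its coordinates could not be set beside these peaks. Peaks are named by position alone. Tests of promoters, gene loci, gene lists and transcription factor motifs, which were planned, were not run, and accessibility at Sox17, named in the study title, was not analysed here. The labels do not say whether the replicates of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may in part be technical. Reads amplified by PCR are not independent molecules, so intervals on counts cover counting error only. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.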

Results

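Accessible chromatin was compared between naive AKP mouse colon cancer organoids and organoid lines grown from tumours of such organoids. The naive group held 3 libraries of AKP organoids. The primary tumour group held 3 libraries of organoid lines. To make these lines, naive organoids were placed in the colon of immunocompetent mice by colonoscopy, organoids were grown from the tumours that formed, and they were passaged until cancer cells alone were left. The total count in peaks was 1185356, 5987545 and 2350525 in naive replicates 1, 2 and 3, and 3594735, 1916819 and 2053202 in primary tumour replicates 1, 2 and 3. The median peak held 15 reads in naive replicate 1, the shallowest library, and 58 in naive replicate 2, the deepest. The strongest 1% of peaks took between 7.67% and 9.71% of the counts of a library.

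The 2 groups had different accessibility profiles. Across peaks, which are not independent replicates, Pearson's r of log CPM was 0.871 to 0.916 between naive libraries, 0.837 to 0.877 between primary tumour libraries and 0.721 to 0.789 between libraries of different groups. The first principal component held 48.3% of the variance and separated the groups. Naive libraries lay between -97.7 and -57.9 on it, and primary tumour libraries between 65.4 and 91.3. The second component held 20.2% and did not separate the groups. Primary tumour replicate 1 lay at -79.1 and naive replicate 2 at -48.7 on it, the 2 deepest libraries, and the others lay between -0.58 and 63.1.

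The comparison of primary tumour with naive organoids asked which regions differed in accessibility in the lines grown from tumours. Growth in the mouse, outgrowth from the tumour and the later passages in culture are shared by all 3 lines. Their effects cannot be told apart here. Of 36179 tested peaks, 2893 (8.0%) were more accessible and 2317 (6.40%) were less accessible in the lines from primary tumours. The median log2 fold change was 1.66 among the peaks that rose and -1.25 among those that fell. At least 2-fold differences were seen at 2569 of the peaks that rose and 1610 of those that fell, at least 4-fold differences at 899 and 365, and at least 8-fold differences at 152 and 44. In 2746 of the peaks that rose all 3 primary tumour libraries lay above all 3 naive libraries, and in 2223 of those that fell they lay below. Among all tested peaks 15.5% were separated in the first way and 15.3% in the second, where chance gives 5% each way (10% either way).

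**Figure D1:**
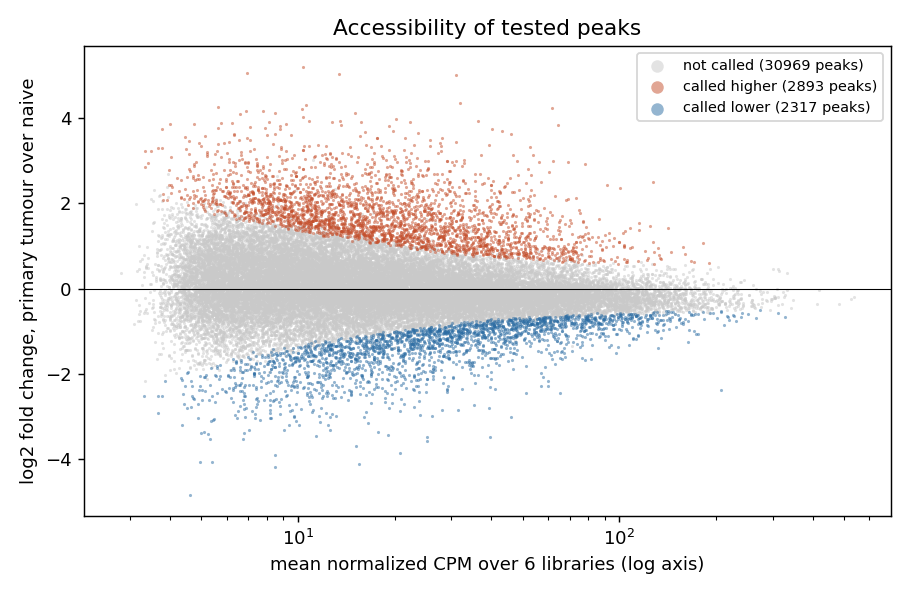
Each point is 1 of 36179 tested peaks, with its mean normalized CPM over 6 libraries on a log axis and its log2 fold change, primary tumour over naive, on the vertical axis. The 2893 peaks called higher lie above 0, the 2317 called lower lie below it, and 30969 peaks were not called.

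Called peaks had a higher authors' score than the rest, whose meaning is not given in the sources used here, and were somewhat wider. Whether strong peaks are only called more readily was not tested for these values. The median score was 41.9 for peaks that rose, 40.6 for peaks that fell and 26.7 for peaks not called, and the median widths were 884, 877 and 838 bp. The median of the mean CPM was 17.97, 26.5 and 15.5 in the same order. Under TMM scaling, gains and losses fell on peaks of different strength. In the weakest of 4 equal bins of mean abundance (median 6.37 CPM) 661 peaks rose and 292 fell, and in the strongest (median 55.7 CPM) 540 rose and 863 fell. With abundance-trended offsets the weakest bin had 563 higher and 436 lower, and the strongest instead had 840 higher and 614 lower. The difference between weak and strong peaks, and the direction of the split among strong peaks, therefore depended on the scaling. Those offsets also narrowed the gap in fold size, with a median log2 size of 1.55 for higher and 1.41 for lower calls. Without them the median sizes of higher and lower calls were 2.16 and 2.25 in the weakest bin, 1.74 and 1.63 in the next, 1.43 and 1.24 in the one after, and 1.02 and 0.85 in the strongest. Without naive replicate 2, the deepest library, edgeR called 1366 peaks higher and 849 lower. With all 6 libraries, a test against a fold change of 2 called 509 and 208.

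The 12 named peaks with the highest fold changes lay on 9 chromosomes and rose between 15.8-fold and 36.5-fold. The highest value was found on chromosome 14 from 27306154 to 27306576. There the normalized count was 20.4 ± 2.57 CPM in primary tumour lines and 0.306 ± 0.530 CPM in naive organoids (SD, n = 3 each), with a log2 fold change of 5.19 (SE 0.65, adjusted p = 7.96e-06, edgeR). The naive value rests on 0, 5 and 0 reads, against 75, 33 and 47 reads in the primary tumour lines. Similar sparse naive signal was seen on chromosome 10 from 87141713 to 87142233, with 1, 6 and 0 naive reads and 70, 68 and 47 reads in primary tumour lines (log2 fold change 5.04, adjusted p = 3.96e-06). On chromosome 19 from 28698280 to 28699604 the normalized count was 60.3 ± 27.9 CPM against 1.92 ± 0.573 CPM (31.98-fold, adjusted p = 4.35e-08). A peak on chromosome 5 from 103794188 to 103794740 had 60.7 ± 8.26 against 3.30 ± 1.05 CPM (log2 fold change 4.34, SE 0.35, adjusted p = 2.09e-08). The strongest of the 12 in primary tumour lines was on chromosome 6 from 31098423 to 31099814, with 116 ± 43.6 against 7.18 ± 3.53 CPM (log2 fold change 4.23, SE 0.34, adjusted p = 5.16e-08). Folds of several of the 12 moved by over 1.5 times when 1 library was left out. Without naive replicate 2 the naive reads at the chromosome 14 peak were all 0, which allows only the statement of an at least 23.8-fold difference (3 counts over the naive libraries left), and the log2 fold change of the first chromosome 10 peak was 6.21.

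The other 7 peaks of this set had log2 fold changes between 3.98 and 4.30. They lay on chromosome 15 from 59962555 to 59963393 and from 58321395 to 58321940, chromosome 19 from 14694854 to 14695391, chromosome 2 from 5242426 to 5242846, chromosome 10 from 44607027 to 44607725, chromosome 13 from 41776063 to 41776756 and chromosome 8 from 36351855 to 36352681. The primary tumour lines differed in the height of some of them. The chromosome 2 peak had 30.5, 4.76 and 11.9 CPM in primary tumour replicates 1, 2 and 3, and the peak at 58321395 on chromosome 15 had 24.5, 4.76 and 9.96 CPM. Both stayed above every naive library, as the rule for named peaks requires. The highest naive values were 2.57 and 1.71 CPM. Without naive replicate 2 the log2 fold changes of this pair were 3.39 and 3.56, those at 14694854 on chromosome 19 and 36351855 on chromosome 8 were 5.02 and 4.58, and without primary tumour replicate 2 that at 59962555 on chromosome 15 was 3.66. The chromosome 2 peak had 4.81 without naive replicate 1, and the peak at 58321395 had 5.30 without naive replicate 3. Without primary tumour replicate 1 neither of them passed the filter, so neither was tested.

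The 12 named peaks with the lowest fold changes lay on 10 chromosomes and were between 10.0-fold and 18.3-fold lower in primary tumour lines. The lowest value was on chromosome 17 from 78509107 to 78509455, with 0.904 ± 0.869 CPM in primary tumour lines and 16.0 ± 2.95 CPM in naive organoids (SD, n = 3 each; log2 fold change -4.19, SE 0.65, adjusted p = 9.08e-05, edgeR). It rests on 1, 1 and 4 reads in the primary tumour lines and 18, 73 and 45 in naive organoids. On chromosome 15 from 54810824 to 54811340 the values were 1.68 ± 1.01 and 29.2 ± 6.06 CPM (log2 fold change -4.12, SE 0.49, adjusted p = 4.32e-06). The strongest naive signal of this set was on chromosome 11 from 4705945 to 4706759, where 72.7 ± 6.62 CPM in naive organoids stood against 6.28 ± 2.78 CPM in primary tumour lines (log2 fold change -3.49, SE 0.31, adjusted p = 5.38e-08). Without primary tumour replicate 3 the log2 fold change of the chromosome 17 peak was -5.24.

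Among the other 9 peaks of this set, log2 fold changes ran from -3.90 to -3.33. Chromosome 15 held another pair, from 82637362 to 82637915 and from 77312718 to 77313249. The rest lay on chromosome 10 from 103177866 to 103178288, chromosome 14 from 100727961 to 100728399, chromosome 5 from 91722102 to 91722626, chromosome 3 from 137595757 to 137596415, chromosome 13 from 96945645 to 96946043, chromosome 9 from 17361994 to 17362577 and chromosome 1 from 164883209 to 164883805. Replicates were close at the chromosome 13 peak, with 1.89 ± 0.422 CPM in primary tumour lines and 20.9 ± 1.11 CPM in naive organoids. They were spread widely at the chromosome 5 peak, with 3.56 ± 3.11 and 46.8 ± 23.2 CPM. Folds that moved by over 1.5 times had log2 values of -4.74 on chromosome 5 and -2.78 on chromosome 9 without primary tumour replicate 1, -4.42 on chromosome 14 without replicate 2 and -4.63 at 82637362 on chromosome 15 without replicate 3.

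**Figure D2:**
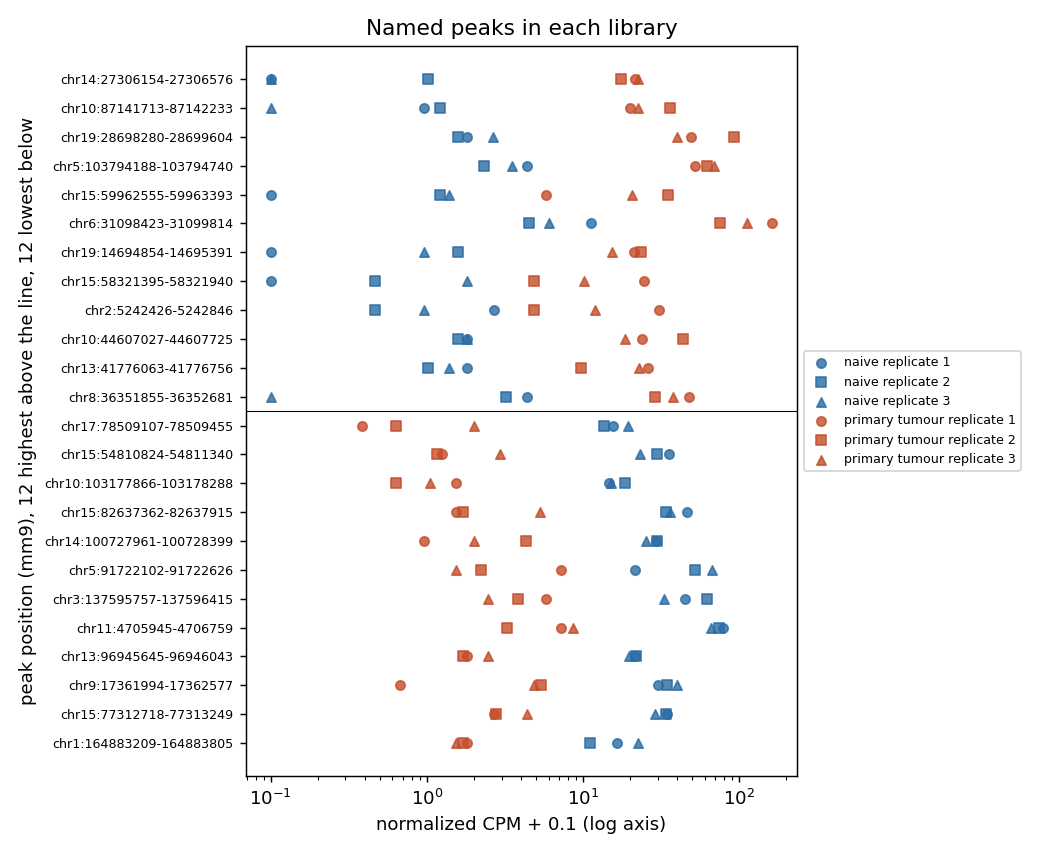
Normalized CPM plus 0.1 on a log axis at the 24 named peaks, 1 point per library, with the 12 highest fold changes above the line and the 12 lowest below it. At each peak the 3 libraries of 1 group lie on 1 side of the 3 of the other, as the rule for named peaks requires. The naive libraries of the chromosome 14 peak at the top hold 0 to 0.919 CPM.

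A pair of strong peaks outside that rule, chosen after their values were seen, had the smallest adjusted p-values in each direction. On chromosome 6 from 54978534 to 54979667, accessibility was 120 ± 13.8 CPM in primary tumour lines and 8.36 ± 0.596 CPM in naive organoids (SD, n = 3 each), a log2 fold change of 3.83 (SE 0.25, adjusted p = 9.02e-10, edgeR). On chromosome 17 from 13500853 to 13502574 it was 67.5 ± 11.6 against 347 ± 7.22 CPM, a log2 fold change of -2.37 (SE 0.19, adjusted p = 2.09e-08).

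Called peaks also lay in runs along the genome. There were 31 runs of at least 4 consecutive peaks that rose, with 143 peaks on 16 chromosomes and a median span of 37.8 kb, and 16 runs of peaks that fell, with 71 peaks on 11 chromosomes and a median span of 42.5 kb. In 1000 shuffles of the calls within chromosome and 10 bins of abundance, a mean of 0.842 runs rose and 0.722 fell, with at most 5 of either. The longest shuffled runs had 6 peaks that rose and 7 that fell. The widest of the longest runs covered 107.67 kb on chromosome 18, from 42845426 to 42953096. Its 7 peaks had log2 fold changes from 1.44 to 3.82, and their summed signal was 292 ± 90.5 CPM in primary tumour lines and 56.6 ± 10.1 CPM in naive organoids (SD, n = 3 each). The tested peaks on either side, starting at 42789195 and 43073573, had log2 fold changes of -0.26 and -0.12 (adjusted p = 0.633 and 0.932, edgeR).

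**Figure D3:**
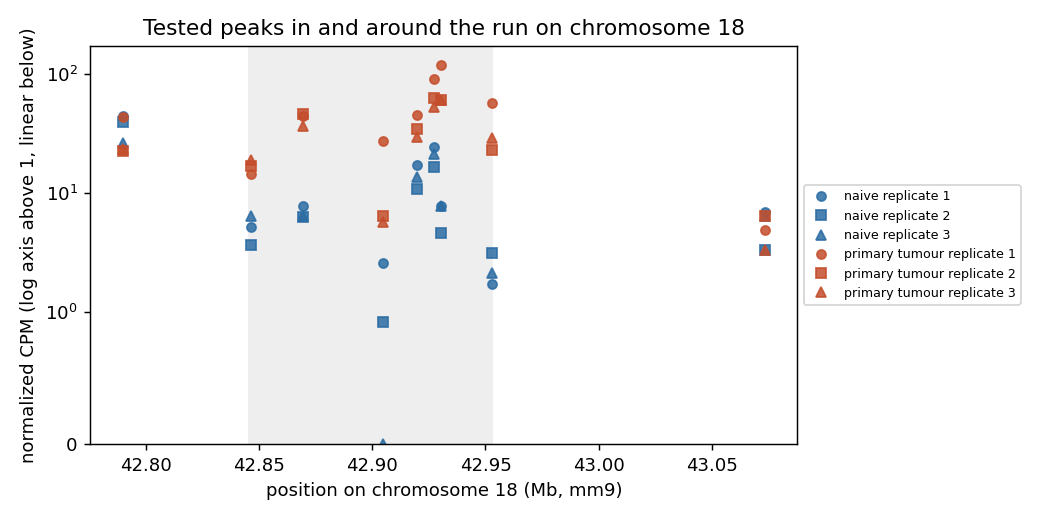
Normalized CPM of each library (log axis above 1, linear below) at the tested peaks in and around the run on chromosome 18, against position in Mb of mm9; shading marks the run. In each of the 7 shaded peaks the 3 primary tumour libraries lie above the 3 naive libraries, and at the neighbours outside the 2 groups overlap.

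Another run of 7 peaks that rose lay on chromosome 12 from 17733251 to 17781008, with a summed signal of 353 ± 59.1 against 131 ± 3.69 CPM. Runs of 6 peaks that rose, within the length reached by shuffles, were found on chromosomes 11, 7 and 9. On chromosome 11 the run went from 54014726 to 54038586, with 213 ± 15.9 against 40.2 ± 13.5 CPM. That on chromosome 7 went from 148148403 to 148195697, with 115 ± 36.9 against 31.6 ± 7.13 CPM. That on chromosome 9 went from 120426669 to 120451709, with 273 ± 17.3 against 85.1 ± 12.2 CPM. The longest run of peaks that fell had 6 peaks, within the length reached by shuffles, on chromosome 16 from 33738882 to 33782808, with 159 ± 32.6 CPM in primary tumour lines and 391 ± 43.4 CPM in naive organoids. A run of 5 peaks on chromosome 14 from 100666715 to 100750412 fell from 169 ± 17.0 to 48.1 ± 1.56 CPM and held the named chromosome 14 peak. A run of 5 peaks on chromosome 4 from 102179013 to 102243422 fell from 131 ± 15.2 to 26.9 ± 8.75 CPM. These sums are over called peaks, so their differences are not tested again here.

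The last comparison asked whether whole chromosomes or large segments moved together in the tumour-derived lines. Chromosome 13 had the highest share of called peaks, 18.4% of 1618 tested, and chromosome X the lowest, 6.63% of 769, apart from chromosome Y with 2 tested peaks and 0 called by edgeR. On chromosome 13, 13.2% of peaks fell and 5.13% rose. On the other autosomes the share that fell was between 3.76% and 8.93%. The median log2 ratio to the naive mean on chromosome 13 was -0.69 in primary tumour replicate 2, -0.17 in replicate 3 and -0.08 in replicate 1, and the naive libraries had an SD of 0.01. In primary tumour replicate 2, every one of 12 windows of chromosome 13 was low, with medians between -0.88 and -0.54, and 78.2% of peaks lay below the median of the library. Without that library 6.37% of chromosome 13 peaks fell, within the range of 1.86% to 6.84% on the other autosomes. Between the groups, the chromosome 13 medians differed by -0.33 (SE 0.15, adjusted p = 0.320, limma). None of 20 chromosomes passed that test, and 0 had an unadjusted p under 0.05. Without primary tumour replicates 1, 2 and 3 in turn, 6, 4 and 3 chromosomes had an unadjusted p under 0.05, with total-count scaling 2 and with trended offsets 4, and again none passed after adjustment.

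Primary tumour replicate 1 stood apart on other chromosomes. Its median log2 ratio was -0.34 on chromosome 5, where 15 of 16 windows were below 0, and -0.22 on chromosome 4. It was 0.27 on chromosome 18, where all 9 windows were above 0 (0.05 to 0.48), and 0.24 on chromosome 19. Over autosomes, the SD of the medians was 0.154, 0.171 and 0.0586 in primary tumour replicates 1, 2 and 3, and 0.0120, 0.0187 and 0.0191 in the naive libraries. The naive libraries lay between -0.03 and 0.07 on every autosome. A genome-wide count without chromosomes 4, 5, 13, 18 and 19 gave 2288 peaks higher and 1849 lower of 27364 tested.

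**Figure D4:**
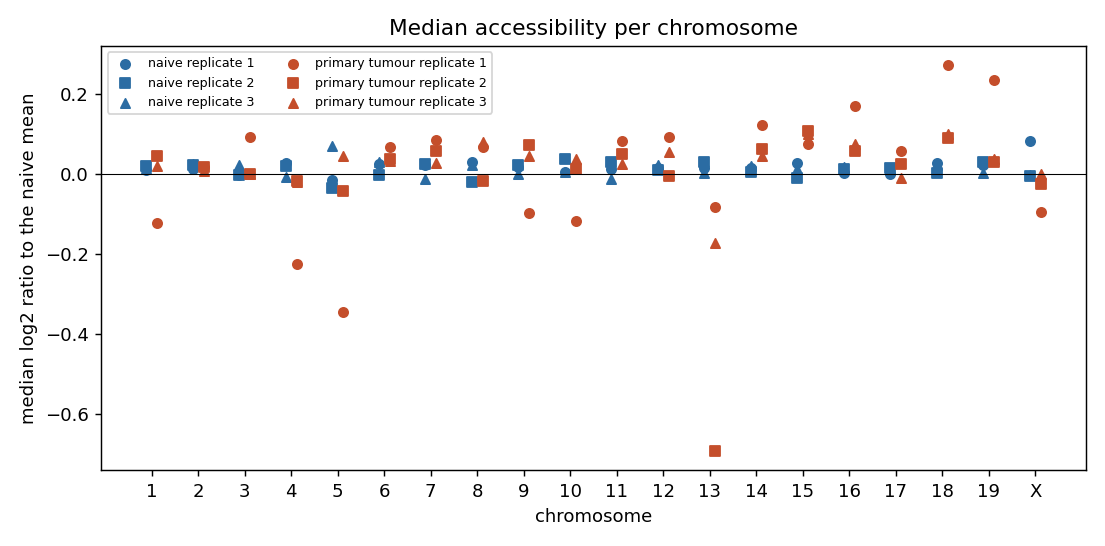
Median log2 ratio of each library to the naive mean over tested peaks (vertical axis) on chromosomes 1 to 19 and X, 1 point per library. The naive libraries stay near 0, primary tumour replicate 2 reaches -0.69 on chromosome 13, and primary tumour replicate 1 reaches -0.34 on chromosome 5 and 0.27 on chromosome 18.

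**Figure D5:**
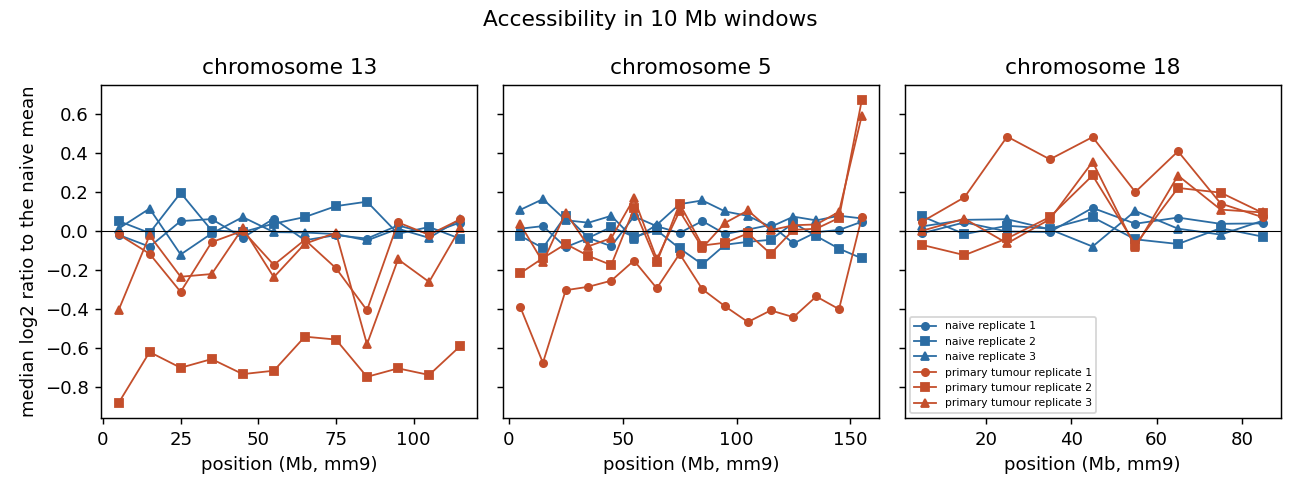
Median log2 ratio to the naive mean in windows of 10 Mb along chromosomes 13, 5 and 18 (position in Mb, mm9), 1 line per library. Primary tumour replicate 2 lies between -0.88 and -0.54 along chromosome 13, and primary tumour replicate 1 lies below 0 in 15 of 16 windows of chromosome 5.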

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

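No peak called in primary tumour against naive organoids changed sign in any alternative in which it was tested. Each of the 24 named peaks kept its call in every alternative in which it was tested (highest adjusted p 0.0205, edgeR without naive replicate 2). All alternatives use the same libraries, in which the 24 were chosen for large folds, so this is no independent support. Of these 24, 22 were tested without primary tumour replicate 1 and 18 with the filter of at least 20 counts in at least 3 libraries. Leaving out 1 library moved the folds of 12 of the 24 by over 1.5 times, 7 of the highest and 5 of the lowest, and other settings moved none by as much. Scaling, filters, DESeq2, trended or window offsets and autosomes alone gave between 4659 and 5340 called peaks, against 5210. Leaving out 1 library gave between 2215 and 5440 called peaks, 1366 to 3033 higher and 849 to 2407 lower; the lowest 3 values came without naive replicate 2, when 41.7% of the calls were shared. The cause was not tested. A test against a fold change of 2 called 717 peaks, 509 higher and 208 lower, because it asks for more than a difference from 0. Without chromosomes 4, 5, 13, 18 and 19, chosen after the data were seen, 4137 peaks were called of fewer tested. The fit with a replicate block called 3539 peaks, 1972 higher and 1567 lower. Deviations of same-numbered libraries had correlations of -0.24, -0.11 and 0.01, and no library correlated best with its own number. The numbers were therefore not taken to pair the libraries. Joining peaks up to 500 bp apart joined none and tests nothing.

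The 5 chromosome medians recomputed here kept their direction. Some others near 0 changed sign with trended offsets, as on chromosome X in primary tumour replicate 3 (0.0006 and -0.07). Chromosome 13 in primary tumour replicate 2 was -0.66 with total-count scaling, -0.75 with trended offsets and -0.54 with a pseudocount of 5 CPM, where other values also shrank. With that pseudocount, primary tumour replicate 1 had -0.29 on chromosome 5, -0.19 on chromosome 4, 0.22 on chromosome 18 and 0.19 on chromosome 19. Chromosome 18 had 0.29 with total-count scaling and 0.32 with trended offsets, and chromosome 19 had 0.25 and 0.26. The trended offsets and the pseudocount were chosen after the data were seen. So was the limma test of windows, which called 5 with all libraries, 3 with total-count scaling, 9 with trended offsets and 0 to 27 with 1 library left out. Promoters, gene loci, gene lists and motifs, with their alternatives, were not run. In simulated counts the test called 19.1% of peaks changed by a log2 fold of 1. There 34149 of 34343 peaks were unchanged and few were called, so the adjusted threshold was stricter than with the 5210 calls here. That share is therefore no estimate of the differences missed with these libraries.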

Other observations

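The limma test of windows, the limits set on the trend and bins of fold sizes, the test on the share of chromosome 13 peaks below the library median and the test of runs were chosen after the data were seen. Under TMM scaling, the medians of some 10 Mb windows were shifted in the same direction in all 3 primary tumour lines. Of 263 windows of 10 Mb, 3 had a median log2 ratio to the naive mean above 0.25 in each of the primary tumour lines, and 4 had one below -0.25 in each. Each of these is measured from the same naive mean. With limma under TMM, 5 of the 263 windows differed between the groups, all among these 7, and 71 had an unadjusted p under 0.05. Of these 5, 3 were higher and 2 lower, whereas trended offsets gave 2 higher and 7 lower. The windows called therefore depended on the scaling. Under TMM their number also depended on single libraries. It was 1, 3 and 2 without naive replicates 1, 2 and 3. Without primary tumour replicates 1, 2 and 3 it was 27, 10 and 0 (68 at an unadjusted p under 0.05). The windows that rose were chromosome 15 from 20 to 30 Mb (mean 0.49 ± 0.08, SD, n = 3; adjusted p = 0.00606, limma), chromosome 12 from 0 to 10 Mb (0.37 ± 0.02; adjusted p = 0.0166) and chromosome 18 from 40 to 50 Mb (0.37 ± 0.10; adjusted p = 0.0245), which holds the run of 7 peaks and lies on a chromosome that was high as a whole in primary tumour replicate 1 (median 0.27). Those that fell were chromosome 13 from 80 to 90 Mb (-0.58 ± 0.17; adjusted p = 0.00684) and chromosome 17 from 90 to 100 Mb (-0.62 ± 0.21, 20 peaks; adjusted p = 0.0156). In primary tumour replicate 2 the chromosome 13 window, at -0.75, was close to its whole chromosome, at -0.69. Chromosome 1 from 0 to 10 Mb (-0.34 ± 0.08) and chromosome 14 from 10 to 20 Mb (-0.29 ± 0.01) did not pass the test.

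The 2 tested peaks of chromosome Y held 32, 56 and 48 reads in naive replicates 1, 2 and 3, and 15, 33 and 57 in primary tumour replicates 1, 2 and 3. As CPM without TMM factors these were 27.0, 9.35 and 20.4, and 4.17, 17.2 and 27.8. The exact binomial 95% interval of primary tumour replicate 1 was 2.34 to 6.88, which covers counting error only.

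Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called peaks as the real grouping, and that was the real grouping itself, with 5210. The highest of the other 9 splits was 0 with edgeR, where between 395 and 2399 peaks had an unadjusted p under 0.05. There are too few splits for a share under 0.05. Each of the other 9 splits mixes both groups, so a difference between the groups adds to the spread within them and lowers the number of calls. Their 0 calls therefore do not show what libraries without a group difference would give.

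Chromosome 13 held the highest share of peaks that fell. In primary tumour replicate 2 the fall was not confined to a part of it, since 78.2% of its peaks lay below the library median and all 12 windows were below -0.5. These limits were set after the values were seen. Closing of many separate peaks along the whole chromosome would give the same values, so it stays open. An offset per library and window lowered the share that fell from 13.2% to 7.42%, within the 4.93% to 8.19% of the other autosomes. That offset removes any shift shared by a window, whatever its cause, so it cannot tell causes of such a shift apart. Fewer copies of chromosome 13 in part or all of the cells of that line may explain the excess. A chromosome-wide fall in accessibility with an unchanged copy number stays open as well. The median ratio of 0.619 in that line, and the growth in the mouse that its group shares, were not tested further.

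More peaks rose than fell, with a larger median size in these libraries. A trend with abundance as the whole cause of the excess of calls is argued against. With trended offsets higher calls outnumbered lower calls by 1.31 to 1 (1.22 to 1.55 with 1 library left out). For the sizes a trend stays open. The difference in median log2 size was 0.41 under TMM, with a jackknife SE over libraries of 0.23. The larger size of gains is therefore uncertain over libraries. With trended offsets the difference was 0.14 (SE 0.034). Under the same offsets it was 0.05, 0.05 and 0.06 without primary tumour replicates 1, 2 and 3, each with a 95% interval that covers 0. These intervals resample 10 Mb blocks, so they do not measure the spread between libraries. A single primary tumour line as the cause of the excess of calls is argued against, since under TMM the ratio was at least 1.26 with each of the 3 left out. For the sizes a single line stays open. The difference was at least 0.24 under TMM with each left out, but with trended offsets each interval covered 0. A need for larger folds at weak peaks is argued against in the stronger 2 of 4 bins of abundance, where the difference under trended offsets was 0.197 and 0.124 (at least 0.108 and 0.10 with any library left out, with intervals above 0), and stays open in the weaker 2, where it was -0.060 and 0.092 (as low as -0.29 and 0.01 without a primary tumour replicate). A difference between the groups may explain the excess of calls, as a hypothesis, while the choice of the peak set and the TMM assumption that most peaks did not change were not tested.

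Peaks that rose lay near each other. Within 50 kb, 559 neighbouring pairs both rose, 3.06 times the mean of 1000 shuffles within chromosome and 10 bins of abundance, which never gave more than 226 (permutation p = 0.000999, the smallest possible), and 340 pairs both fell, against at most 169. This argues against a clustering of strong peaks with more power as the cause. Gain or loss of large segments and local variation within groups are argued against by the covariance of log2 differences, which was 0.138 (SE 0.00885) under 50 kb and 0.00824 (SE 0.00390) at 1 to 5 Mb, while deviations within groups alone would give 0.0177 under 50 kb. Coordinated opening or closing of domains of the size of these runs in the tumour-derived lines may explain it, as a hypothesis found and tested on the same data, and small copy-number changes of that size stay open.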
